A study of Drosophila melanogaster with 22 samples.

How the data were processed

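Chromatin accessibility was measured by bulk ATAC-seq in isolated hearts of adult Drosophila melanogaster. The 22 libraries fall into 6 groups, taken from the sample titles. Hearts of w1118 flies, a white-eyed laboratory strain, were taken at 1 week and at 5 weeks of age (3 libraries each). RNAi against LamC was compared with attp2 controls (4 libraries each), and RNAi against the B-type lamin, called LamB in the labels and Lam in the gene annotation, with attp40 controls (5 and 3 libraries), all at 1 week. Per the labels' design text, RNAi was driven by Hand-Gal4, a heart driver. That text counts 3 LamC and 4 LamB knockdown libraries where the sample labels give 4 and 5, and all labelled libraries were used. Nothing in the labels says whether libraries of a group came from separate pools of flies, so the p-values measure the spread between these libraries, which may be partly technical. The sex of the flies is not given in the sources used here. The files carry dates whose meaning is not given: all attp40 and LamB RNAi libraries are from July except attp40 replicate 3, from 14 February, and the libraries of each of the other comparisons lie within 1 month of each other.

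Each library came with a peak list of its own in narrowPeak format. Per the submitters' processing notes, Bowtie2, SAMtools, Picard and MACS2 were used with genome build dm6. The versions, the settings and any shift of reads for the transposase are not given in the sources used here. The authors' lists give each peak a fold enrichment over local background, a −log10 p-value and a −log10 q-value, all relative to that library. Reads were not used here and the sequencing depth is unknown. The number of peaks that pass a threshold grows with depth, so the deposited lists, of 8491 to 12395 peaks, are not comparable as they stand.

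For this reason each list was reduced to its 8491 strongest peaks by the authors' −log10 p, the length of the shortest list. The reduced lists were merged with bedtools 2.31.1 (minimum overlap 1 bp), and regions with a peak in at least 3 of the 22 libraries were kept, which left 9850 regions. The score of a region in a library was computed from the rank of its strongest peak, from 1 for the strongest peak of the list down to 0 where the list held no peak. This rank score is relative within a library, says nothing of the total amount of open DNA, and a score of 0 means that the library had no peak in the region or only one ranked below its 8491 strongest. Coordinates are those of the files (dm6), written from base 1.

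The gene table used here (RefSeq annotation of the Release 6 assembly, the assembly behind dm6) holds gene spans without strand. Regions were therefore assigned to protein-coding genes with an end, start or stop, within 500 bp, called gene ends below, then to genes whose body they overlapped, then to the gene with the nearest end within 5 kb. Of the 9850 regions, 5837 lay at a gene end, 3288 in a gene body, 445 within 5 kb of a gene end and 280 had no gene. Exons and introns are not told apart. A motif search that had been planned needs a genome sequence and was not run. All 337 members of the 17 gene lists, which cover heart function, chromatin, metabolism, stress, immunity and the other cell types a dissected heart can hold, were found in the gene table, 4 of them under a newer symbol.

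The comparisons, tests and gene lists were chosen before the data were examined. The 3 comparisons were 5 weeks against 1 week in w1118, LamC RNAi against attp2, and LamB RNAi against attp40. None of them share a library. Scores were tested with limma 3.58.1 (R 4.3.3, moderated with a trend) in a fit of all 22 libraries, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The spread of a region is therefore 1 estimate over all 6 groups, those outside the comparison included. Tests of the difference between changes were contrasts in the same fit. Gene lists and genome compartments were tested with limma's camera, with a preset correlation of 0.01 and adjustment over all lists and comparisons, and again with an estimated correlation and with fry. Further measures were the regions with a peak in every library of a group and none of the other (Fisher's exact test), the Jaccard index of covered bases within and between groups, and the correlation of score differences between comparisons, the last 2 with exact permutation tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

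The limma step was tested on simulated data built from the 9850 real regions, with 200 regions of intermediate mean score shifted in each of 20 runs. The noise was the residuals of the fit, shuffled over libraries, which are smaller than the full spread, so recovery may be overstated. A shift of 0.4 was recovered in 73.9% of cases for the age comparison, 88.0% for LamC and 82.8% for LamB. A shift of 0.2 was recovered in 7.00%, 17.8% and 14.9% of cases. The false share of calls was 11.2% for age, 3.30% for LamC and 5.36% for LamB, so it lay well above 5% for age and slightly above it for LamB. Many regions called with age had no peak in any young library or in any old one. Shifts of such regions, or of others with a low or high mean score, were not simulated, so these shares may not hold for them.

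The rule for named regions took, per comparison, up to 12 higher and 12 lower regions past the threshold with the largest score differences, non-overlapping groups and a named gene at a gene end or in the gene body, 1 per gene. Where fewer passed, the smallest p-values filled up to 6 per direction, given as values only. It also took up to 4 members of each list, the lamin genes, and regions shared by age and a knockdown. Called regions without such a gene, named below because few regions passed in the knockdowns, were chosen after their values were seen.

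The alternatives were ranking by fold enrichment, lists of 4245 peaks, lists as long as the shortest of each comparison with regions and a fit from its libraries alone, no filter on regions, summit-centred windows, a peak covering at least 50% of its region, fits on the libraries of a comparison alone, library weights, no trend, the major chromosome arms only, a replicate block, and leaving out each library in turn. After seeing the data, the share of peaks at gene ends and the median peak width were added as covariates, and LamB replicates 3 and 4, which stood apart from the other libraries, were left out together.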

Results

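Accessible chromatin was profiled in fly hearts in 6 groups, with the stated purpose of finding regions whose accessibility changes both with age and after knockdown of either lamin, the intermediate filament proteins that line the inner nuclear membrane. Flies carry LamC, the A-type lamin, and Lam, the B-type lamin. The deposited lists held 11034 ± 370.3 peaks (SD, n = 3) in w1118 at 1 week and 11338 ± 930.1 (n = 3) at 5 weeks, 10366 ± 1031 (n = 4) in the attp2 control and 9875 ± 988 (n = 4) after LamC RNAi, and 9217 ± 642 (n = 3) in the attp40 control and 10304 ± 804 (n = 5) after LamB RNAi. They covered 4445 to 7303 kb. Of 24 comparisons of library measures between the groups none passed adjustment (exact permutation tests, two-sided, lowest adjusted p = 0.343). Those of age could not pass, since 3 against 3 libraries cannot go below an exact p of 0.1. The number of peaks on unplaced or Y scaffolds did not overlap between the groups of any of the 3 comparisons. Its exact permutation p was the smallest each allows (0.1 for age, 0.0286 for LamC and 0.0179 for LamB). In the equal-length lists 53.3% of the 9850 regions had a peak in all 22 libraries, and score correlations between libraries of one group ran from 0.867 to 0.949.

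The knocked-down genes themselves were open in every group. The region at the end of LamC (2R, 14574344 to 14576278) had a rank score of 0.690 ± 0.097 (SD, n = 4) after LamC RNAi and 0.783 ± 0.022 (n = 4) in its control, with a limma adjusted p of 0.653. The regions at both ends of Lam scored 0.686 ± 0.085 (n = 5) and 0.760 ± 0.027 after LamB RNAi, against 0.696 ± 0.079 (n = 3) and 0.789 ± 0.054 in the attp40 control, both with a limma adjusted p of 1. RNAi acts on transcripts, so these values do not check the knockdown.

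With age, 130 of the 9850 regions changed, 60 higher and 70 lower at 5 weeks (limma adjusted p under 0.05). Regions inside Mmp2, a matrix metalloproteinase, Dys, the dystrophin that links the muscle cytoskeleton to the matrix, dally, a cell-surface heparan sulfate proteoglycan, and Calx, the sodium/calcium exchanger, were among those that rose. Regions at or in ct, slp2, Klf15, chinmo and mid were among those that fell. The largest rise was 0.444 ± 0.087 (limma SE) in mim, an actin and membrane regulator, and the largest fall −0.523 ± 0.112 in ct.

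Mean scores of the 12 named regions that rose were 0 to 0.294 at 1 week and 0.347 to 0.656 at 5 weeks. In mim (2R, 6961080 to 6962442) the score was 0.472 ± 0.157 (SD, n = 3) at 5 weeks and 0.028 ± 0.022 (n = 3) at 1 week, with a limma adjusted p of 0.00931. Mmp2 (2R, 9678226 to 9678951) went from 0.029 ± 0.030 to 0.435 ± 0.128 with the same adjusted p. The Dys region (3R, 19476265 to 19477145) had no peak in the 3 young libraries and scored 0.369 ± 0.177 in the old ones (adjusted p = 0.000392). That p-value rests on the spread over all 22 libraries, not on that of the old ones alone. In the attp2, attp40 and both RNAi groups mean scores there were only 0 to 0.012, with SDs of 0 to 0.020. A region in HnRNP-K, an RNA-binding protein gene (2R, 20596529 to 20597598), and one between Cpr49Aa and Cpr49Ab, cuticle protein genes (2R, 12376863 to 12378161), were likewise without a young peak and reached 0.347 ± 0.068 and 0.373 ± 0.237. Scores of dally rose by 0.399, of the phosphatidylinositol 4-kinase gene Pi4KIIalpha by 0.399, of the phosphatase gene PpD6 by 0.396, and of Ire1, the sensor of unfolded protein in the endoplasmic reticulum, by 0.388. The remaining rises were 0.385 in toc, 0.369 in bbg and 0.362 in mura, a RING finger gene, and adjusted p over the 12 ran from 0.000392 in Dys to 0.0455 in mura.

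The 12 named regions that fell lost most of their rank. In ct, a homeobox gene (X, 7651418 to 7652185), the score was 0.582 ± 0.116 (SD, n = 3) at 1 week and 0.058 ± 0.056 (n = 3) at 5 weeks (limma adjusted p = 0.0189). At slp2, a forkhead gene (2L, 3836512 to 3836867), it went from 0.536 ± 0.110 to 0.052 ± 0.063 (adjusted p = 0.0308). The zinc finger genes sens-2 (2L, 6833538 to 6834056) and chinmo (2L, 1656740 to 1657496) went from 0.662 ± 0.010 to 0.238 ± 0.172 and from 0.453 ± 0.107 to 0.099 ± 0.058. The end of Klf15 (X, 4771397 to 4772285), a regulator of nephrocyte differentiation, went from 0.396 ± 0.136 to 0.033 ± 0.056 (adjusted p = 0.0261). Scores fell by 0.454 in pxb, by 0.380 in nuf, by 0.379 in Plp, the pericentrin-like protein gene, and by 0.367 in RapGAP1. In stj, which encodes an auxiliary calcium channel subunit, and at CHKov2 they fell by 0.319 and 0.287, and in the formin gene Fhos the score went from 0.360 ± 0.150 to 0.061 ± 0.105. Some of these regions were also low in 1-week attp2 or attp40 hearts, so a low score there is not particular to old hearts. Means in attp2 and attp40 were 0.016 and 0.245 at Klf15, 0.081 and 0.215 in nuf, and 0.092 and 0.240 in Fhos. They were 0 and 0.083 in stj and 0.115 and 0 at CHKov2. In ct, slp2, pxb, sens-2, Plp, RapGAP1 and chinmo they were 0.247 to 0.703. A second region in Dys (3R, 19508938 to 19509241) fell by 0.211, so Dys held changes in both directions.

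**Figure D1:**
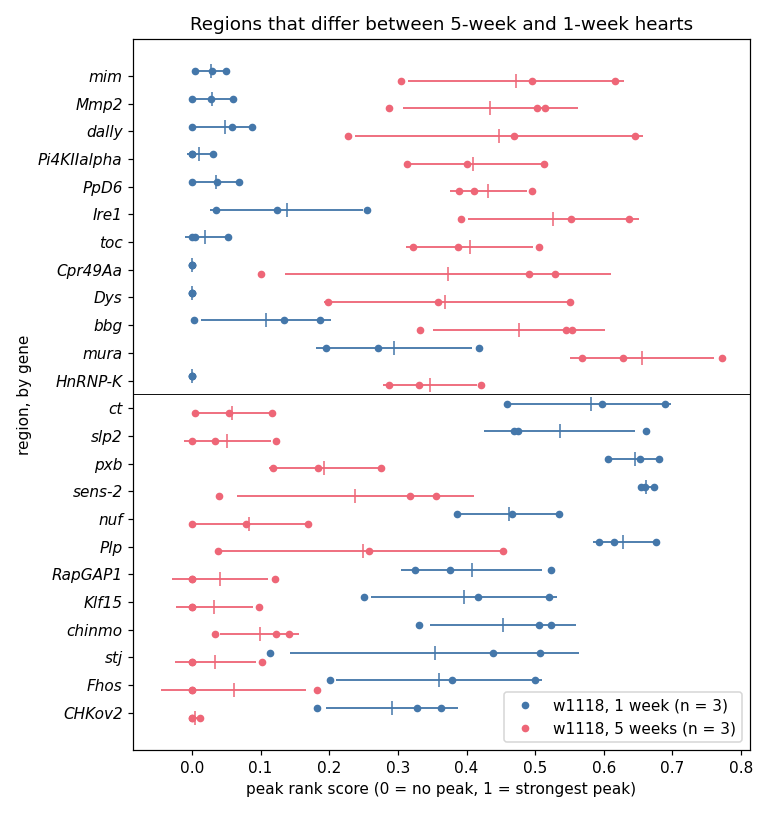
Peak rank scores of the 24 named regions that differed between ages in w1118 hearts; points are libraries (n = 3 per age), ticks are means and bars are SDs, with regions higher at 5 weeks above the line and lower ones below it. The scores of the 2 ages do not overlap in any of these regions, by the rule that chose them.

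The changed regions lay at gene ends less often than the other regions. Of the 130, 39 (30.0%) were at a gene end against 59.3% of all regions (Fisher's exact test, two-sided, p = 1.47e-11), and 65 (50%) were inside gene bodies against 33.4%. The test treats regions as independent and equally easy to call, which was not checked. As a set, the 5837 regions at gene ends averaged 0.493 ± 0.015 (SD, n = 3) at 5 weeks and 0.482 ± 0.007 (n = 3) at 1 week (camera adjusted p = 0.0255, and 0.644 with an estimated correlation, range over the alternatives 0.000741 to 0.644). Regions over 2 kb from any gene end averaged 0.314 ± 0.018 and 0.334 ± 0.002 (adjusted p = 0.0397, and 0.644 with an estimated correlation, range 0.0023 to 0.644). Both calls ended without replicate 1 or 2 at 1 week (adjusted p of 0.0704 and 0.0643 for gene ends, 0.0932 and 0.0953 for distant regions) or without replicate 1 or 3 at 5 weeks (0.0909 and 0.464, 0.0965 and 0.491). Peaks present in all 3 old libraries and no young one were found in 101 regions and the reverse in 110. Per region, 3 against 3 libraries cannot go below p = 0.1 in Fisher's exact test. With all deposited peaks in place of equal-length lists the numbers were 199 and 109. Peak sets overlapped slightly more within ages (Jaccard index 0.757) than between them (0.734), a difference of 0.0230 with an exact permutation p of 0.1, one-sided, the smallest 10 splits allow.

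Of the gene lists, 2 passed camera's test with age, sarcomere genes and cardiac transcription factors, both with lower means, and neither passed with an estimated correlation. The 78 regions of sarcomere and myofibril genes averaged 0.248 ± 0.086 (SD, n = 3) at 5 weeks and 0.329 ± 0.011 (n = 3) at 1 week (limma camera adjusted p = 0.00132, and 0.672 with an estimated correlation, range over the alternatives 1.46e-05 to 0.852). None of the 78 passed alone, also when adjusted over the list alone. The lowest p-values were in sls, the titin-like gene (−0.368, adjusted p = 0.153), Tm1 (−0.364, adjusted p = 0.170), Zasp66 (−0.168, adjusted p = 0.255) and Mlc1 (−0.219, adjusted p = 0.277). The 3 old libraries averaged 0.287, 0.307 and 0.149, and without the last, replicate 3, the list gave an adjusted p of 0.427.

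The 60 regions of cardiac and mesodermal transcription factors averaged 0.374 ± 0.016 (SD, n = 3) in old hearts and 0.426 ± 0.009 (n = 3) in young ones (limma camera adjusted p = 0.0126, and 0.458 with an estimated correlation, range over the alternatives 0.00679 to 0.458). Without w1118 replicate 3 at 5 weeks the adjusted p was 0.0874, and without replicate 2 at 1 week 0.0683. The end of mid (2L, 5461079 to 5461792), a T-box gene of heart development, was the only member to pass over all regions, falling from 0.946 ± 0.019 to 0.756 ± 0.054 (limma adjusted p = 0.0147), and adjusted over the list alone 1 member rose and 2 fell. Its neighbour H15, also a T-box gene, differed by −0.117 (adjusted p = 0.0733), a region in Mef2, the muscle regulator, by −0.102 (adjusted p = 0.205), and a region in svp, a nuclear receptor gene, by 0.326 (adjusted p = 0.0564).

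**Figure D2:**
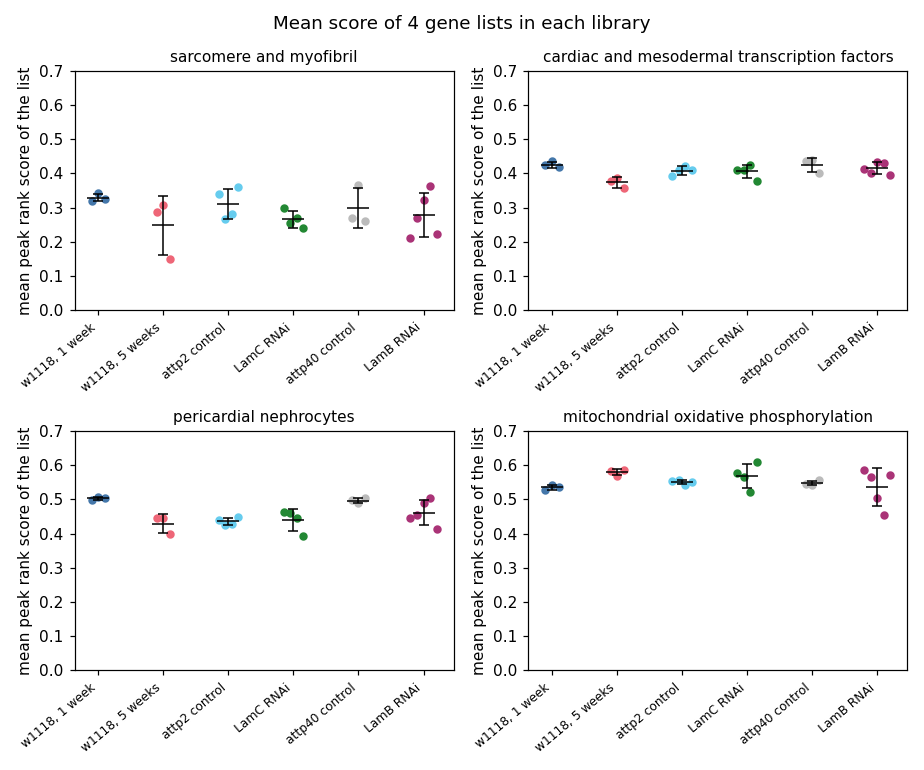
Mean peak rank score of the regions of 4 gene lists in each of the 22 libraries, by group; points are libraries, wide ticks are means and bars are SDs. The sarcomere list in the 3 libraries from 5-week hearts lies at 0.149 to 0.307, against a mean of 0.329 at 1 week.

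Genes of other cell types did not lie in one direction with age, and none of their lists passed camera. The 17 regions of pericardial nephrocyte genes averaged 0.429 ± 0.027 (SD, n = 3) at 5 weeks and 0.504 ± 0.004 (n = 3) at 1 week (camera adjusted p = 0.134), with Klf15 lower and sns, the nephrin-like gene, at −0.318 (limma adjusted p = 0.0553). Hemocyte genes averaged 0.225 ± 0.018 and 0.290 ± 0.009 (camera adjusted p = 0.236), with a region near the GATA factor gene srp (3R, 16004851 to 16005459) lower by −0.344 (limma adjusted p = 0.0313). At 1 week this srp region also had no peak in any attp2 library and averaged 0.219 in attp40. Fat body genes averaged 0.387 ± 0.019 and 0.347 ± 0.026 (camera adjusted p = 0.597). The list differences were 0.0186 for neurons and glia (adjusted p = 0.864), −0.0455 for somatic muscle identity (0.546), −0.0354 for trachea and epidermis (0.399) and −0.0505 for germline (0.522).

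Mitochondrial oxidative phosphorylation genes, mostly nuclear gene ends, averaged 0.580 ± 0.009 (SD, n = 3) at 5 weeks and 0.536 ± 0.007 (n = 3) at 1 week, above in all 3 old libraries, with a camera adjusted p of 0.134. Ion channel and calcium handling genes differed by −0.0408 (camera adjusted p = 0.361), and by fry's mixed test the list as a set departed from no change in either direction (adjusted p = 2.89e-06). So did the lists of nephrocyte genes (adjusted p = 0.00506), cardiac transcription factors (0.00678) and extracellular matrix genes (0.0478). In each of these lists only 1 region passed over all regions. Fry tests whether the members of a list move one way on balance, or in its mixed form in either direction, without comparing the list with other genes. Calx rose by 0.238 ± 0.028 (limma SE, adjusted p = 7.82e-05), and Ca-alpha1D, the L-type calcium channel gene, differed by −0.326 (adjusted p = 0.0865) and Shal by −0.278 (adjusted p = 0.177). Extracellular matrix genes differed by −0.0299 (camera adjusted p = 0.399) although Mmp2 rose. Differences were 0.0106 for innate immunity (adjusted p = 0.699), where a region in PGRP-LB, a negative regulator of the Imd pathway, rose by 0.309, and 0.0170 for chromatin silencing (0.597), where a region near the Polycomb group gene Psc fell by 0.245. They were 0.0004 for nuclear envelope and lamina genes (0.917, where camera's direction was lower although mean and median lay above 0), 0.0067 for insulin, TOR and lipid genes (0.635) and −0.0085 for stress response and proteostasis genes (0.836).

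The number of age-changed regions depended on the fit, the regions and the length of the lists. Fitted on the 6 w1118 libraries alone, 20 regions passed, 3 of them among the 130, with regions also drawn from these 6 libraries alone, and lists as long as the shortest of them, 1 passed, with lists of 4245 peaks 27 passed, and with library weights 224 passed. Without w1118 replicate 3 at 1 week 67 passed and without replicate 3 at 5 weeks 61. With the replicate number as a block in the fit of the 6 libraries no region passed. Of the 38 named regions past the threshold, 0 passed in the fit of the 6 libraries, with or without the block.

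LamC knockdown was compared with its attp2 control to ask which regions depend on the A-type lamin. Changes were few: 15 regions passed, 8 higher and 7 lower (limma adjusted p under 0.05). Among genes, a region in Zasp52, a Z-disc gene, and those at the ends of Rim2 and Abp1 rose, and those at Prx6c, a peroxiredoxin gene, Syx6, Kah and Pi3K68D fell. The largest changes were on DNA that is not part of the assembled arms: a region of the unplaced scaffold Un_DS484314v1 (1291 to 2374) had a peak in 4 of 4 knockdown libraries, at a score of 0.996 ± 0.004 (SD, n = 4), and in 0 of 4 controls.

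The Zasp52 region (2R, 15781110 to 15781775) scored 0.319 ± 0.076 (SD, n = 4) after LamC RNAi and 0.015 ± 0.031 (n = 4) in the control (limma adjusted p = 0.0463). At Rim2 and Eno, genes of a mitochondrial carrier and enolase (2L, 1723313 to 1724575), the score was 0.341 ± 0.082 against no control peak (adjusted p = 0.0328), and attp2 was the only group without one, with means of 0.185 and 0.190 in w1118 at 1 and 5 weeks, 0.138 in attp40 and 0.275 after LamB RNAi. At Abp1 and Tgi (3L, 13485985 to 13487274), genes of an actin-binding protein and a Hippo pathway factor, it was 0.921 ± 0.023 against 0.763 ± 0.042 (adjusted p = 0.00181). Prx6c (2R, 10418055 to 10418716) went from 0.826 ± 0.097 in the control to 0.152 ± 0.155 (adjusted p = 0.000252), and Syx6, a syntaxin gene (2R, 11222319 to 11223033), from 0.820 ± 0.067 to 0.554 ± 0.071 (adjusted p = 0.00637). A region in Kah, a zinc finger gene (3L, 586416 to 586781), fell by 0.170 (adjusted p = 0.00692) and had a peak in the 4 controls and, outside them, in 1 w1118 library at 1 week only, and one at Pi3K68D and twy (3L, 11788859 to 11790286), at a lipid kinase gene, fell by 0.150 (adjusted p = 0.0201). At Pi3K68D attp2 stood apart at 0.916, since w1118 at both ages, attp40 and LamB RNAi had means of 0.756 to 0.802, near the 0.767 after LamC RNAi. Values short of the threshold were 0.219 at PIG-H (adjusted p = 0.0522), 0.326 at the stress gene Gadd45 (0.0929), 0.168 in ec (0.106), −0.386 at Ugt301D1 (0.0700) and −0.114 in luna (0.0717).

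Outside genes, a region of X (95371 to 95831) rose by 0.277, with a limma adjusted p of 1.41e-05. Y scaffold regions at 13401 to 13981 and at 21024 to 21528 of Y_CP007111v1_random rose by 0.861 and 0.221, each with a peak in 4 of 4 knockdown and 0 of 4 control libraries (adjusted p = 0.000986 for both). Regions near 4E-T, on chromosome 4, and near esg, a Snail family gene, fell by 0.450 and 0.551 (adjusted p = 0.000986 and 0.00637). Some of these differed among the other strains as well: the unplaced scaffold region scored 0.078 in w1118 at 1 week, 0.934 in attp40 and 0.981 after LamB RNAi, and Prx6c had no peak in w1118 and scored 0.503 in attp40. The mean of the 5 Y regions was higher by 0.216, which came from the 2 called regions, with a median difference of 0 (camera adjusted p = 0.000714, and 0.0174 with an estimated correlation, range over the alternatives 0.00127 to 0.0174). Peaks on unplaced or Y scaffolds numbered 9.50 ± 0.577 (SD, n = 4) after knockdown and 4.75 ± 0.957 (n = 4) in the control (exact permutation p = 0.0286, two-sided, adjusted p = 0.343). Pericentromeric regions averaged 0.460 ± 0.056 (SD, n = 4) and 0.446 ± 0.013 (n = 4, camera adjusted p = 0.934), with differences of 0.0039 for X (adjusted p = 0.934) and −0.0124 for chromosome 4 (0.340). A peak in all knockdown and no control library was found in 18 regions and the reverse in 10, each with a Fisher's exact p of 0.0286, and 0 of these passed adjustment. That p is the smallest these libraries allow, so this few regions could not pass adjustment over all regions.

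Sarcomere genes were lower after LamC RNAi as a list, 0.266 ± 0.024 (SD, n = 4) against 0.311 ± 0.045 (n = 4) in the control (camera adjusted p = 0.00278), while their one member past the threshold, Zasp52, was higher, also when adjusted over the list alone. With an estimated correlation the adjusted p was 0.672, with a range over the alternatives from 0.000255 to 0.672, and it was 0.0984 and 0.117 without attp2 replicate 1 or 4 and 0.0515 without LamC replicate 4. Somatic muscle identity genes differed by −0.0565 (camera adjusted p = 0.380). The other 15 lists had camera adjusted p of 0.361 or more. These include germline genes, at 0.0327, hemocyte genes, at 0.0296, cardiac transcription factors, at −0.0027, and nephrocyte genes, at 0.0038. Fitted on the 8 libraries alone, 4 regions passed, 3 of them among the 15.

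LamB knockdown was compared with its attp40 control to ask the same of the B-type lamin, and 18 regions passed, 11 higher and 7 lower (limma adjusted p under 0.05). The end of mid fell, as did regions at y, the yellow pigmentation gene, at EMC2B, at hoka and in Mob2. Regions in fru, the sex determination gene, in Mkp3, a MAP kinase phosphatase gene, and in RhoGEF2 rose. Ranked by fold enrichment, 7 regions were higher and 9 lower.

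At mid (2L, 5461079 to 5461792) the score was 0.677 ± 0.077 (SD, n = 5) after LamB RNAi and 0.866 ± 0.026 (n = 3) in the control, lower in 5 of 5 libraries (limma adjusted p = 0.0254). The region at y (X, 361313 to 361928) went from 0.445 ± 0.109 to 0.062 ± 0.085 (adjusted p = 0.0236), EMC2B (3R, 16991626 to 16992381) from 0.682 ± 0.067 to 0.270 ± 0.161 (adjusted p = 0.0407), and Mob2 (3L, 11523279 to 11523824) from 0.859 ± 0.019 to 0.669 ± 0.080 with the same adjusted p. At hoka, a septate junction gene (3L, 4898789 to 4899377), a peak was found in the 3 controls and none of the 5 knockdown libraries. The regions in fru (3R, 18507751 to 18507996) and Mkp3 (3L, 19071329 to 19071633) had peaks in 5 of 5 knockdown and 0 of 3 control libraries, at 0.355 ± 0.128 and 0.243 ± 0.118 (adjusted p = 0.0138 and 0.0337), and RhoGEF2 (2R, 17037913 to 17038486) went from 0.046 ± 0.049 to 0.202 ± 0.058 (adjusted p = 0.0496). Values short of the threshold were 0.371 in Csk (adjusted p = 0.0767), 0.315 in Roc2 (0.0593), 0.345 in the lipophorin receptor gene LpR1 (0.108) and −0.434 at PGRP-LA (0.0648). The nephrocyte gene sns differed by −0.336 (adjusted p = 0.0673).

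Without a gene, regions at 1352 to 1822 and 11514 to 12197 of the Y scaffold Y_CP007111v1_random were present in 5 of 5 knockdown and 0 of 3 control libraries, and rose by 0.825 and 0.522 (limma adjusted p = 2.95e-09 and 0.00374). A region of 2R (21848033 to 21848763) rose by 0.608 (adjusted p = 4.15e-07), and one near cwo, a circadian repressor gene (3R, 10384490 to 10384996), by 0.491 (adjusted p = 0.0029). The mean of the 5 Y regions was higher by 0.381 and their median difference was 0.455, with 2 of the 5 called (camera adjusted p = 1.31e-12, and 5.13e-05 with an estimated correlation, range over the alternatives 8.64e-13 to 5.13e-05). Pericentromeric regions averaged 0.453 ± 0.056 (n = 5) and 0.454 ± 0.005 (n = 3, adjusted p = 0.934), and regions of X and chromosome 4 differed by −0.0051 and −0.0165 (adjusted p = 0.934 for both). In w1118 at 1 week the Y regions at 1352 and 11514 scored 0.968 and 0.982, and neither had a peak in attp2 or LamC RNAi hearts. Peaks on unplaced or Y scaffolds numbered 13.2 ± 0.837 (SD, n = 5) and 6.67 ± 0.577 (n = 3, exact permutation p = 0.0179, two-sided, adjusted p = 0.343). The sex of the flies is not given in the sources used here.

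**Figure D3:**
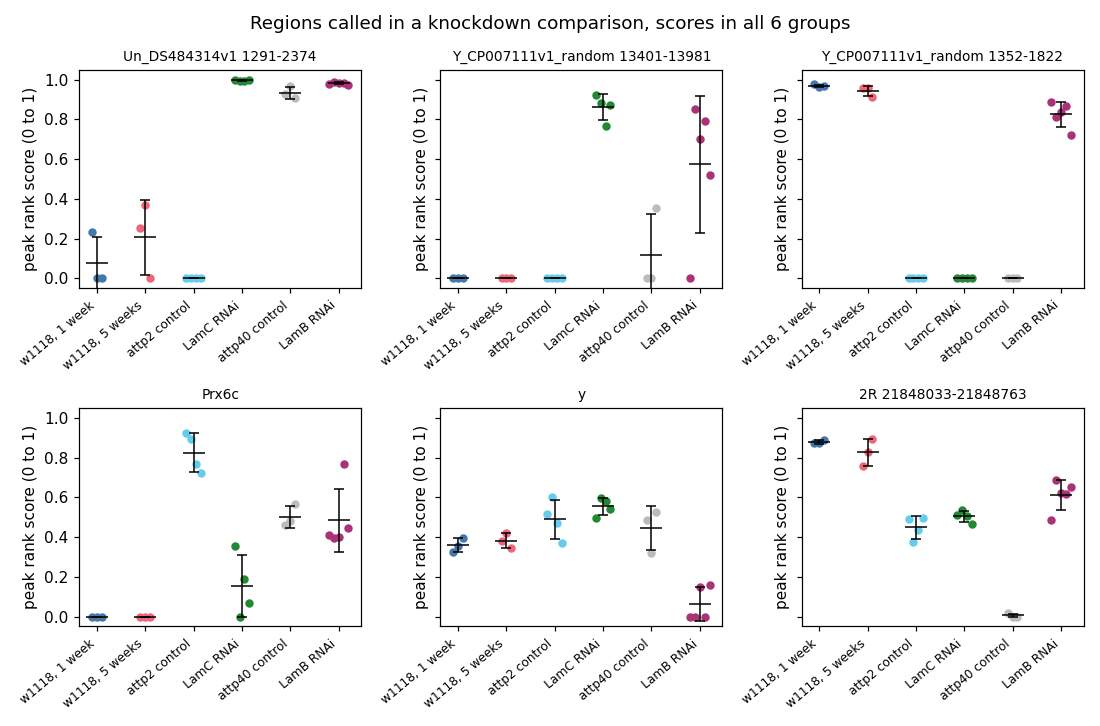
Peak rank scores (0 to 1) of 6 regions that passed the test in the LamC or LamB comparison, in all 22 libraries by group; points are libraries, wide ticks are means and bars are SDs, and panels are titled by gene or by position. The Y scaffold region at 1352 has scores of 0.720 to 0.885 after LamB RNAi and no peak in attp40, attp2 or LamC RNAi hearts.

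No gene list passed after LamB RNAi (camera, 0 of 17, and 0 at an unadjusted p under 0.05, with 0 by an estimated correlation and 0 by fry, although nephrocyte genes passed fry's mixed test with an adjusted p of 0.0478). Sarcomere genes averaged 0.278 ± 0.065 (SD, n = 5) and 0.299 ± 0.058 (n = 3, camera adjusted p = 0.466), cardiac transcription factors 0.415 ± 0.017 and 0.425 ± 0.021 (adjusted p = 0.597) and nephrocyte genes 0.461 ± 0.036 and 0.496 ± 0.007 (adjusted p = 0.466). The lowest adjusted p was 0.361, for ion channels (−0.0260) and innate immunity (0.0205). Replicates 3 and 4 stood apart, with sarcomere means of 0.321 and 0.364. Without both, an alternative chosen after seeing the data, 3 lists were lower: sarcomere genes, 0.234 ± 0.030 (n = 3, camera adjusted p = 0.000276), ion channels, 0.299 ± 0.006 (adjusted p = 0.0128), and nephrocyte genes, 0.437 ± 0.021 (adjusted p = 0.0495).

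A peak in all LamB knockdown and no control library was found in 15 regions and the reverse in 20, each with a Fisher's exact p of 0.0179, and 0 passed adjustment. As for LamC, that p is the smallest the libraries allow, so this few regions could not pass. With all deposited peaks the numbers were 40 and 4. The Jaccard index within groups minus that between them was 0.00396 for LamC and −0.00869 for LamB, neither past the threshold (exact permutation p = 0.257 and 0.643, one-sided). Fitted on the 8 libraries alone 7 regions passed, 4 of them among the 18, and 8 to 10 passed without LamB replicate 1, 4 or 5 or attp40 replicate 3. Without attp40 replicate 3, whose date is months before the others, 9 regions passed, among them the region of 2R and both Y regions, and none of the 8 named at genes, mid included.

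Among regions common to age and a lamin knockdown, the question of the series, 1 was found, the end of mid. It was lower by 0.190 ± 0.040 (limma SE) at 5 weeks and by 0.189 ± 0.035 after LamB RNAi, and its scores did not overlap between the groups of either comparison. One shared lower region compares with 0.0497 by chance from 70 and 7 calls (Fisher's exact test, two-sided, p = 0.0487, among 12 such overlaps). After LamC RNAi the same region scored 0.861 ± 0.028 (SD, n = 4) against 0.806 ± 0.045 (n = 4). The controls at 1 week differed by strain, with means of 0.946 in w1118, 0.866 in attp40 and 0.806 in attp2. The attp2 range, 0.754 to 0.849, overlapped that of w1118 at 5 weeks, 0.694 to 0.790. The region at mid passed under 13 of 19 alternatives for age and 12 of 22 for LamB, with limma adjusted p up to 0.478 and 0.784. The LamB call was lost without attp40 replicate 3. Its difference ran from −0.0683 to −0.380 for age and from −0.127 to −0.379 for LamB. No region was shared by age and LamC or by LamC and LamB.

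**Figure D4:**
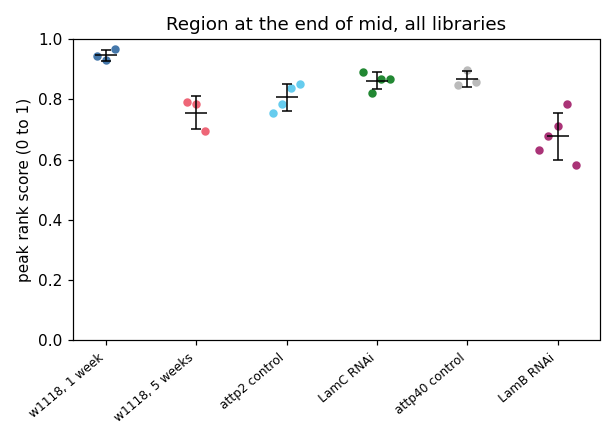
Peak rank score (0 to 1) of the region at the end of mid in all 22 libraries by group; points are libraries, wide ticks are means and bars are SDs. Scores lie at 0.694 to 0.790 in 5-week hearts and 0.581 to 0.784 after LamB RNAi, below their own controls.

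Across all regions, which are not independent replicates, the score differences with age correlated weakly with those after LamB RNAi (r = 0.238, exact permutation p = 0.146, two-sided, over 1120 labellings) and after LamC RNAi (r = 0.169, p = 0.140, over 1400), and those of the 2 knockdowns did not track each other (r = −0.0276, exact permutation p = 0.835). Without LamB replicate 4 the correlation of age and LamB was 0.333 (exact permutation p = 0.0286), and without replicates 3 and 4 it was 0.364 (p = 0.03). Without attp40 replicate 2 it was 0.102 (exact permutation p = 0.548). The covariances were 0.00184 for age and LamB, 0.00127 for age and LamC and −0.00016 for both knockdowns (exact permutation p = 0.0732, 0.0514 and 0.796). The 70 regions that fell with age averaged −0.0388 after LamB RNAi, 46 lower and 14 higher (exact permutation p = 0.0179, the smallest these libraries allow, adjusted p = 0.234 over the tests of this kind). After LamC RNAi the same 70 averaged 0.0012 (exact permutation p = 0.943). The 60 regions that rose with age averaged 0.0128 after LamB RNAi and 0.0141 after LamC RNAi (exact permutation p = 0.536 and 0.286). The reverse was measured with age, signed by the direction after the knockdown. The 18 regions called after LamB RNAi averaged −0.0097, 6 in the same direction and 9 opposite (exact permutation p = 0.2). The 15 called after LamC RNAi averaged 0.029, 9 in the same direction and 2 opposite (exact permutation p = 0.1, the smallest 3 against 3 libraries allow).

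The changes after LamC and after LamB RNAi differed from each other in 7 regions (limma contrast, adjusted p under 0.05), among them Prx6c, the region at Abp1 and Tgi, and the region near cwo. The change with age differed from that after LamC RNAi in 39 regions (22 to 71 without a library) and from that after LamB RNAi in 15 (8 to 43 without a library). Of 100 labellings of the libraries, 2 gave as many as 39 and 7 as many as 15.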

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

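The splits of the libraries and the tests of cell type share, strain and silent chromatin were chosen after the results were seen. The covariate tests were chosen after the data, but before their own results, were seen.

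Accessibility changed differently after LamC and after LamB RNAi in 7 regions, each by a limma test of the difference between the changes. The value given is the LamC change minus the LamB change. It was 0.949 on the unplaced scaffold Un_DS484314v1 (1291 to 2374) and −0.825 on the Y scaffold Y_CP007111v1_random (1352 to 1822), both with an adjusted p of 1.85e-06. It was −0.553 in the region of 2R from 21848033 to 21848763 (adjusted p = 0.000508) and 0.271 in the region of X from 95371 to 95831 (adjusted p = 0.00382). At genes it was 0.204 at Abp1 and Tgi (adjusted p = 0.0118), −0.582 near cwo (adjusted p = 0.0145) and −0.654 at Prx6c (adjusted p = 0.0339). On the unplaced scaffold the knockdowns were close, with mean scores of 0.996 after LamC and 0.981 after LamB RNAi, and the controls apart, at 0 in attp2 and 0.934 in attp40, a level that leaves little room for a rise. In the region of 2R the knockdowns had 0.504 and 0.613 and the controls 0.449 and 0.005, so in both regions the difference lies mostly between the control strains. At Prx6c the scores were 0.152 after LamC RNAi and 0.826 in attp2, 0.484 after LamB RNAi and 0.503 in attp40. Near cwo they were 0.101 and 0.192 for LamC and 0.751 and 0.260 for LamB, at Abp1 0.921 and 0.763 and 0.816 and 0.862, and on X 0.286 and 0.009 and 0.008 and 0.003. The Y region had a peak in the LamB RNAi hearts only among these 4 groups. Among 100 labellings of the libraries, all but the real one drawn at random, only the real one gave 7 regions and the highest other gave 6. A count of 7 was rare among these labellings, which does not exclude chance.

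A library lay far from the others of its group in 2 of the 48 groups of values examined, where chance alone gives about 1 in 20 groups. In the Zasp52 region attp2 replicate 4 scored 0.0615 and the other 3 controls had no peak. In the Mkp3 region LamB replicate 2 scored 0.0347 and the other 4 LamB libraries 0.272 to 0.325.

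The 130 regions that changed with age are the first pattern, and library quality was weighed as a technical explanation. With the share of peaks at gene ends as a covariate, 105 of the 130 stayed past the threshold in the same direction, and with the median peak width 129 did, which argues against either measure as the whole cause. The 6 libraries allow only 10 splits, too few for a share under 0.05: the real split gave 130 regions and 2 lists, the highest other 6 and 1, and only 1 split, the real one, gave as many of either. Age itself stays open, as do differences between the libraries that neither measure captures.

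Sarcomere genes were lower as a list with age and after LamC RNAi by camera's preset correlation (adjusted p = 0.672 with an estimated correlation in both). A smaller share of heart muscle nuclei was taken to raise the genes of all other cell types. With age nephrocyte genes differed by −0.0741 (SE 0.0156) and fat body genes by 0.0402 (SE 0.0188), the lowest and highest of 6 lists. These lists moved apart, but neither passed (camera adjusted p = 0.134 and 0.597). Scores are also relative within a library, so a smaller muscle share need not raise every other list. A smaller muscle share therefore stays open. After LamC RNAi the lowest of the 6 lists, trachea and epidermis, differed by −0.0014 (SE 0.0346) and the highest, germline, by 0.0327 (SE 0.0194), which decides nothing. Library quality stays open in both: with the share of peaks at gene ends as a covariate the list difference was −0.0562 in place of −0.0814 for age (69.0% kept) and −0.0358 in place of −0.0452 for LamC (79.3% kept). Age and LamC stay open as well, and for LamC chance cannot be excluded, since 17 of 35 splits gave at least 1 list (highest other 2).

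The third pattern is the regions called after either knockdown, those on the Y and unplaced scaffolds among them. An opening of pericentromeric and Y chromatin alike would raise pericentromeric regions as much as Y regions. After LamB RNAi the pericentromeric difference plus 2 standard errors over libraries reached 0.0499. The mean Y difference of 0.381 less 2 standard errors over the 5 Y regions was 0.0845, so the 2 sets did not rise alike there. After LamC RNAi the same bounds, 0.0716 and −0.117, leave it open. The standard errors measure unlike spreads, over libraries and over regions. The 2 Y regions called after LamB RNAi also varied by strain, with 0.968 and 0.982 in w1118 at 1 week and no peak in attp2. The bounds therefore do not decide what the LamB knockdown itself does. Of the 33 called regions 18.2% also differed between control strains outside the comparison, against 1.44% of the others, each region counted once per knockdown (Fisher's exact test, two-sided, p = 7.51e-06). A strain or transgene difference may therefore contribute to part of them. The strain contrasts came from the same fit, so a region of small spread passes more easily in both tests, which Fisher's test takes as independent. The control strains also differ in the dates of their files, so strain and date cannot be told apart. The other called regions did not pass the test between those strains, which does not show that they are alike there. The knockdowns themselves stay open, since every knockdown library carries both the transgene and the knockdown.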

How the results depend on the processing

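The 2 covariates and the removal of LamB replicates 3 and 4 were chosen after seeing the data. The correlation of age and LamC and the Y scaffold sets kept their direction and side of the threshold under the alternatives run for them. The Jaccard difference for age stayed above 0, and its exact permutation test cannot go below p = 0.1. The correlation of LamC and LamB and the Jaccard differences of both knockdowns lay on either side of 0 without passing. Of the named regions past the threshold, 0 of 38 for age, 1 of 11 for LamC and 0 of 11 for LamB passed under every alternative other than leaving out a library, and all kept their direction. The cause of the changes below was not tested, except that shorter lists and fewer libraries leave less to test. Motif tests were not run.

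For age, 130 regions became 20 with the comparison's own libraries, 224 with library weights, 27 with lists of 4245 peaks and 1 with the comparison's own libraries, regions and shortest list together. Leaving out a library gave 61 to 171, with 61 without w1118 replicate 3 at 5 weeks and 67 without replicate 3 at 1 week. For LamC, 15 became 4 with its own libraries and 7 with its own libraries, regions and shortest list, and 12 to 22 without a library. For LamB, 18 became 10 with summit windows, 7 with its own libraries, 9 without trend, 9 with a peak covering 50% of the region and 5 with its own libraries, regions and shortest list, which is of 8491 peaks as before, and 8 to 24 without a library (10, 9 and 8 without LamB replicate 1, 4 or 5, and 9 without attp40 replicate 3).

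Nothing in the labels says that the replicate numbers pair the libraries. Correlations of the deviations of same-numbered libraries were 0.0237, 0.0638 and 0.147 for age, −0.0490, 0.0385, −0.0408 and −0.274 for LamC and 0.139, 0.213 and 0.0841 for LamB. Not every library correlated best with its own number: replicates 2 and 3 did for age and for LamB, and replicate 2 for LamC. The dates the files carry, whose meaning is not given, put w1118 replicate 1 on 20 March at 1 week and 31 March at 5 weeks, replicate 2 on 1 and 2 April and replicate 3 on 25 and 26 March, so a day effect shared by a number is not excluded. With the replicate number as a block, 0 regions passed for age, 1 for LamC and 0 for LamB. These fits used the libraries of each comparison alone, which already gave fewer regions without a block (counts above). The loss is therefore not due to the block alone.

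The 7 regions of the LamC and LamB difference became 16 with library weights, 14 with lists of 4245 peaks, 13 without trend, and 6 to 23 without a library (11 and 14 without LamC replicate 4 or attp2 replicate 4, 12 and 23 without attp40 replicate 1 or 2). The 39 of age and LamC became 64 with weights and 12 with lists of 4245 peaks, and 22 to 71 without a library (22 and 25 without LamC replicate 1 or 2, 25 and 22 without attp2 replicate 2 or 3, 71 without 5-week replicate 1). The 15 of age and LamB became 8 without LamB replicates 3 and 4, 40 with weights, 47 without a filter, 29 without trend, 40 with 50% coverage and 37 ranked by fold, and 8 to 43 without a library (8 without LamB replicate 5, 27 and 24 without 1-week replicate 2 or 3, 43 and 32 without 5-week replicate 1 or 2).

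Regions with a peak in one group only numbered 211 for age, 81 with lists of 4245 peaks and 297 to 399 without a library. They were 28 for LamC, 16 with all deposited peaks, 13 at a −log10 q of 5 or more and 38 to 57 without a library. They were 35 for LamB, 13 with lists of 4245 peaks, 22 with 50% coverage and 47 to 100 without a library. Fewer libraries make the requirement easier to meet. The correlation of age and LamB was 0.364 without LamB replicates 3 and 4 (exact permutation p = 0.0300) and 0.102 to 0.333 without a library (0.333, p = 0.0286, without LamB replicate 4).

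The 2 lists for age became 0 with an estimated correlation, 0 by fry, 0 ranked by fold and 0 with the gene-end share, and 0 to 2 without a library. The sarcomere list then had adjusted p of 0.672, 0.491, 0.852 and 0.102, and 1.46e-05 to 0.427 without a library. The cardiac transcription factors had 0.458, 0.0918, 0.152 and 0.127, and 0.00814 to 0.0874. The 1 list for LamC became 0 under the same 4 alternatives, with sarcomere adjusted p of 0.672, 0.629, 0.545 and 0.0785, and 0 to 1 list without a library (0.000255 to 0.117). The 0 lists for LamB became 3 without replicates 3 and 4, and 0 to 1 without a library (1 without LamB replicate 4, sarcomere genes, adjusted p = 0.0207). The 2 compartments for age became 0 with an estimated correlation (0.644 for gene ends and for distant regions), and 0 to 2 without a library (0.000741 to 0.464 and 0.0023 to 0.491). For LamC 1 compartment became 2 and 3 without LamC replicate 2 or 3, with a range of 1 to 3.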

Other observations

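The regions and genes in the next 2 paragraphs were chosen after their values were seen, as were the splits of the libraries.

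Some genes held regions that changed with age in opposite directions, as Dys did. In lilli, a transcription elongation factor gene, a region of 2L from 2935803 to 2936280 fell by 0.261 (limma adjusted p = 2.15e-05) and one from 2922118 to 2922665 rose by 0.335 (adjusted p = 0.0261). A second region in mim (2R, 6947765 to 6948493) rose by 0.221 (adjusted p = 0.000285), like the first. Near tara 2 regions fell, by 0.372 and 0.154 (adjusted p = 0.00853 and 0.0214). Regions in sima, the hypoxia-inducible factor gene, and shot, a spectraplakin gene, rose by 0.184 and 0.276 (adjusted p = 0.0189 and 0.0436). On chromosome 4, regions in Cadps, a regulator of vesicle release, and pho, a Polycomb recruiter gene, rose by 0.288 and 0.198 (adjusted p = 3.72e-05 and 0.00697). A region in zormin, a sarcomere protein gene that is not on the sarcomere list, fell by 0.179 (adjusted p = 0.0320), and regions near croc and pdm2 fell by 0.324 and 0.305 (adjusted p = 0.0343 and 0.0146).

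Several regions called after a knockdown varied widely among the other groups. The region of 2R from 21848033 to 21848763, higher after LamB RNAi, averaged 0.878 in w1118 at 1 week, 0.826 at 5 weeks, 0.449 in attp2, 0.504 after LamC RNAi, 0.005 in attp40 and 0.613 after LamB RNAi. The end of y averaged 0.359 to 0.554 in the 5 groups without LamB RNAi and 0.062 with it, and EMC2B 0.469 to 0.691 in those 5 groups and 0.270 with it. The region at hoka had a peak in the 3 attp40 libraries and in no other library.

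Other splits of the libraries were counted for each result. For LamC, 1 of 35 splits, the real one, gave as many regions (real 15, highest other 7), the smallest share that 35 splits allow. Many counts were made after the results were seen, so this makes chance less likely for the count without excluding it. Nor can chance be excluded for the compartments (19 of 35, real 1, highest other 4) or for the regions with a peak in one group only (2 of 35, real 28, highest other 29). For LamB, 3 of 56 splits gave as many regions (real 18, highest other 52), so chance cannot be excluded for the count. The split with 52 set LamB replicates 1, 3 and 4 against the other 5 libraries, which points to a structure of these samples other than the knockdown. Chance cannot be excluded for the LamB compartments (42 of 56, real 1, highest other 5) or regions with a peak in one group only (5 of 56, real 35, highest other 47). For the LamB lists the real count is 0, so all 56 of 56 splits give as many (highest other 7) and the count decides nothing.

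For age the 10 splits are too few for a share under 0.05, with 5 giving as many compartments (real 2, highest other 3) and 1 as many regions with a peak in one group only (real 211, highest other 56). For the difference between the age and LamC changes 2 of 100 labellings, the real one included, gave as many regions (real 39, highest other 80). Such counts were rare among these labellings, but chance is not excluded, and the labelling with 80 points to a structure of the samples. For age and LamB 7 of 100 did (real 15, highest other 33), and chance cannot be excluded.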
